A study of Homo sapiens with 92 samples.

How the data were processed

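Polyadenylated RNA of 39 core, 36 margin and 17 brain samples was made into libraries with the Illumina TruSeq v2 kit, per the labels, after tissue was broken up with steel beads in Qiazol. The authors deposited a table of FPKM values for each group, with gene symbols and a column per library. Per the submitters' processing notes, reads were aligned with TopHat2 to hg19; versions, the tool that made the FPKM values, its annotation and its filters are not given in the sources used here. Whether the 3 tables were normalized together is not given either. Values of rare genes in each library lie on steps of single reads (85.61% of 231975 low values within 0.1 of a whole read), which gave relative depths of 0.684 to 1.501; FPKM sums averaged 757095 ± 102249 in core, 756389 ± 78107 in margin and 775855 ± 66062 in brain. The precision of low values was therefore that of few reads, and absolute depth was unknown.

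The core table held 55941 lines and the others 55937, with 50051 symbols in all 3 and 4 not. Per group, 27 symbols had been turned into dates and were left out, as were 390 symbols of X-inactivation and Y-linked genes. Of the symbols, 508 stood on several lines, of which the highest value per library was kept. In 3 core libraries these lines held copied values (100% of repeated symbols, against at most 0.813% elsewhere). Repeated symbols were set to missing there, so that HLA-B, C4A, C4B and RPS18, among others, have n = 36 in core in the comparison of genes. List scores, camera, sample weights, splits and simulations used the core mean of the gene in place of these missing values. Of 49661 symbols kept, 19353 with an FPKM of at least 1 in at least 17 samples were tested, of which 14524 were protein-coding by name and 3512 had no match in the name tables (GENCODE 29 and RefSeq on GRCh38, used for names only). Exact zeros stood in genes with a group median of at least 20 FPKM, 517 values in core, 280 in margin and 92 in brain, and were kept.

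Groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), all 3 groups in a single fit, with trend and robust empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested. A gene was called at adjusted p under 0.05 and a change of at least 2-fold. For members of gene lists, "rose" and "fell" refer to adjusted p under 0.05 alone, and counts adjusted over the list alone are given beside them. Medians of log2 changes over all genes were taken per comparison, and the calls were repeated with median-of-ratios scaling. Calls in both tumour groups against the same brain samples were set against simulated unchanged groups and against brain samples split into sets of 8 and 9.

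The 29 gene lists were fixed before the data were examined: neuron, inhibitory interneuron, glutamate receptor and postsynaptic density, mature oligodendrocyte, oligodendrocyte progenitor, astrocyte, microglia, monocyte and macrophage, myeloid, lymphocyte, B and plasma cell, endothelial, mural, ependymal and choroid plexus, red blood cell, proliferation, hypoxia, extracellular matrix, glioma stem, proneural, classical and mesenchymal glioma, antigen presentation, chemokine, complement, reactive astrocyte, immediate early, ribosomal and oxidative phosphorylation genes. Of 421 members 417 were found. List scores were compared by a two-sided permutation test with 100000 resamples, adjusted by Benjamini-Hochberg over 87 differences, and lists were also tested with camera at a preset correlation of 0.01 and at an estimated correlation. An adjusted p of 2.56e-05 is the smallest these permutations gave. Scores of 3 subtype lists and 9 cell type lists were related within margin and within core by Pearson's r and Spearman's rho with permutation p-values adjusted over 54 relations, without shared members, without the 2 farthest samples and within title series. For these relations 6.75e-05 (r) and 0.000108 (rho) are the smallest adjusted values the permutations gave.

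Genes were named by a rule fixed beforehand. It took, per comparison, the 4 largest changes each way among called genes with a mean of at least 5 FPKM in the higher group, up to 3 members of each list with the largest change, members that went against their list, genes highest in margin, and 10 genes always looked at. Some genes the rule names are not reported here. Samples were grouped by the labels, and letters that open the sample titles were used as possible batches. Series A had 13 core, 10 margin and 8 brain samples, and series B 23 core and 23 margin samples. Series B pools samples whose descriptions differ in form (16 and 7 core, 14 and 9 margin), which the covariate kept apart. Another series had 3 samples of each group, and a further series 6 brain samples only. Title series and tissue were thus partly confounded in comparisons with brain. No label ties samples to patients, so no blocking by patient was done. Alternatives were other pseudocounts, filters and scalings, title series as a covariate, each series alone, sample weights, other fits, other list scores, and sets without the copied or zero values.

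The fit was tested on simulated data over 19353 genes. Of genes changed 4-fold, 92% (higher) and 86% (lower) were called from core to brain, 84% and 80% from margin to brain, and 94% and 82% from core to margin. Of unchanged genes 0% were called, but this was fixed in advance, as the group means of each gene had been set equal. It therefore does not measure false calls, and the rates for changed genes leave out random differences between group means. Of genes changed 2-fold 0% were called in each comparison, as the log2(FPKM + 1) scale shrinks the change, and 54% to 76% reached adjusted p under 0.05. For core against brain, the list test found a shift of 1 SD in 93% of simulated scores. It falsely found a shift in 2% of scores without one. These scores had the same SD in each group, whereas real spreads differed (proliferation SD 0.0735 in brain and 1.32 in core). The rates therefore do not cover unequal spreads. The test of differing relations found a difference of 0.7 in r in 93.5%, and falsely found one in 6.0% of simulated relations that did not differ. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.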

Results

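Polyadenylated RNA was sequenced from 92 human tissue samples. Per the labels, 39 came from the contrast-enhancing core of gliomas, 36 from the non-enhancing margin that is bright on FLAIR, and 17 from non-neoplastic brain. The core takes up contrast agent in magnetic resonance imaging, whereas the margin is the surrounding tissue that does not. The series asks how the molecular and cellular make-up of the margin differs from that of the core and of brain, and whether this depends on the transcriptional subtype of the tumour. All values were FPKM (fragments per kilobase, scaled to sequencing depth) per gene and library, so absolute depth was unknown; steps of single reads at low values gave depths between 0.684 and 1.501 relative to the middle of the set. A log2 change below is the difference of group means of log2(FPKM + 1), which understates the change of genes with low values. The labels do not tie samples to patients, so p-values measure the spread between samples, some of which may share a patient.

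The first component of the expression values followed the tissue. It held 34.1% of the variance, and group membership explained 68.8% of it. Brain samples had a mean of -82.2 ± 17.8 (SD, n = 17), margin samples -23.1 ± 51.0 (n = 36) and core samples 57.2 ± 24.6 (n = 39). Margin samples ran from -93.1 to 80.7, across most of the span from brain to core. Mitochondrially encoded genes held 22.8 ± 3.83% of the FPKM sum in brain, 15.6 ± 5.78% in margin and 9.26 ± 5.36% in core. The 10 most abundant genes of a library held 34.8 ± 4.57%, 25.1 ± 5.11% and 21.3 ± 4.93% of the sum, in the same order. The median log2 change over all 19353 genes tested was 0.34 from brain to core, 0.18 from brain to margin and 0.16 from margin to core. Where the median of a gene list is given below, it is relative to these shifts.

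**Figure D1:**
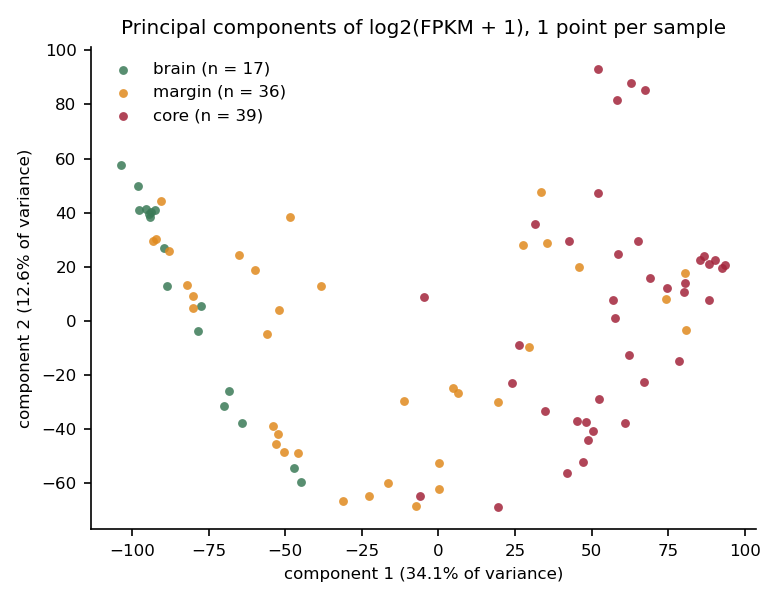
Each point is a sample, placed by its values on the first (x axis) and second (y axis) principal component of log2(FPKM + 1), in arbitrary units, and coloured by group. Brain samples lie between -103 and -44.9 on the first component and core samples between -6.04 and 93.6, while margin samples spread over both ranges.

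Core samples held less RNA of neurons and myelinating cells than non-neoplastic brain, and more RNA of the mesenchymal, matrix, hypoxia, cell division and macrophage lists. SLC17A7, the vesicular glutamate transporter of excitatory neurons, averaged 153 ± 91.6 FPKM in brain (SD, n = 17) and 4.20 ± 12.6 in core (n = 39), a log2 change of -5.74 (SE 0.59, adjusted p = 2.13e-14). CHI3L1, a secreted glycoprotein made by reactive glia and macrophages, averaged 22.99 ± 7.82 FPKM in brain and 2910 ± 2784 in core, a log2 change of 5.77 (SE 0.59, adjusted p = 1.79e-14), and lay above the brain median in 37 of 39 core samples. In all, 3000 genes were called higher and 1821 lower in core. At its preset correlation camera called 12 lists higher and 6 lower in core than in brain, 12 and 5 in margin than in brain, and 8 and 7 in core than in margin, and at an estimated correlation 0 in each. Median-of-ratios scaling, which centres the bulk of genes, turned this balance to 1709 higher and 2593 lower.

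The scores of the neuronal, mature oligodendrocyte and astrocyte lists fell in core. In the neuron list 15 of 15 tested members fell, also when adjusted over the list alone, and 14 fell at least 2-fold. The list score, the mean of log2(FPKM + 1) over members, fell by 4.36 (SE 0.37, permutation adjusted p = 2.56e-05, the smallest that 100000 resamples and 87 differences gave). The median member lay at -5.25 relative to the shift of all genes, and that of the mature oligodendrocyte list at -3.51. VSNL1, a neuronal calcium sensor, and CAMK2A, a kinase of excitatory synapses, fell by 5.85 and 5.57 on the log2 scale. In the inhibitory interneuron list 10 of 12 members fell (11 adjusted over the list alone), among them CCK (-5.43), SST (-4.78) and PVALB (-3.91), and 2 did not pass. In the glutamate receptor and postsynaptic density list 9 of 12 fell, led by the NMDA receptor subunit GRIN1 (-5.53), 1 rose (NLGN1, 0.90) and 2 did not pass. All 15 members of the mature oligodendrocyte list fell, each at least 2-fold and also adjusted over the list alone. OPALIN fell by 5.12, and MBP, a main protein of myelin, went from 7620 ± 7718 FPKM in brain to 1237 ± 2948 in core (log2 change -4.14, SE 0.70, adjusted p = 1.91e-07). The astrocyte list was mixed, with 5 of 15 lower, 2 higher and 8 not passing, and the same counts adjusted over the list alone. The connexin GJB6 (-4.10) and the glutamate transporter SLC1A2 (-3.30) fell, while the filament protein GFAP (1.21) and the transcription factor SOX9 (1.76) rose. Its score fell by 0.73 (adjusted p = 0.00441). The scores of the interneuron, glutamate and mature oligodendrocyte lists fell by 2.56, 1.49 and 2.95 (adjusted p = 2.56e-05 each). With an estimated correlation between genes, camera's adjusted p for these 5 lists was 0.357 to 0.576, so none was called by that test.

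Of the oligodendrocyte progenitor list, 4 of 14 members rose, 2 fell and 8 did not pass (the same adjusted over the list alone). PTPRZ1, a receptor phosphatase of progenitors and glioma cells, rose by a log2 change of 2.84 and GPR17 fell by 1.68. The score difference of 0.28 did not pass (adjusted p = 0.336). In the list of nuclear genes of oxidative phosphorylation, 6 of 18 fell and 12 did not pass, with the same counts adjusted over the list alone. The complex I subunit NDUFB8 fell by 1.30 and the score by 0.30 (adjusted p = 0.000605, or 0.574 from camera with an estimated correlation). Sample titles fall into series, which may be batches. Within the 13 core and 8 brain samples of the largest title series that spans all groups, called series A, that score differed by -0.0012 (permutation adjusted p = 0.993), and the astrocyte score by -0.44 (permutation adjusted p = 0.0735).

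Lists of tumour state rose in core almost throughout. In the reactive astrocyte and acute phase list 13 of 13 members rose at least 2-fold (13 adjusted over the list alone), led by the acute phase protease inhibitor SERPINA3, from 8.44 ± 6.72 to 675 ± 538 FPKM (log2 change 6.02, SE 0.44, adjusted p = 8.79e-21). The mesenchymal glioma list had 19 of 20 members higher (19 adjusted over the list alone), with CD44 (4.81) and TGFBI (5.04). The extracellular matrix list had 17 of 18 higher (17 adjusted over the list alone), with TIMP1 (5.12), TNC (5.08) and COL4A1 (4.25). These lists overlap: 5, 4 and 3 tested members of the mesenchymal, matrix and reactive lists also stand in another list. All 20 proliferation genes rose at least 2-fold (20 adjusted over the list alone), including CENPF (3.57), RRM2 (3.40) and MKI67, the standard histological marker of dividing cells, from 0.0326 ± 0.0426 to 10.2 ± 13.2 FPKM (log2 change 2.64, SE 0.39, adjusted p = 8.46e-09). Of the hypoxia list 14 of 17 rose (14 adjusted over the list alone). VEGFA, the main angiogenic factor induced by low oxygen, averaged 14.9 ± 6.20 FPKM in brain and 823 ± 1030 in core, and ADM (3.96) and CA12 (3.53) rose too. The glioma stem and progenitor list had 10 of 14 higher (10 adjusted over the list alone), with NES (3.83), ID3 (2.997), FABP7 (2.85) and SOX2 (2.12). Score differences were 3.83 for reactive astrocytes, 3.15 for matrix, 2.72 for mesenchymal, 2.54 for proliferation, 1.84 for hypoxia and 1.66 for stem genes (adjusted p = 2.56e-05 each), and list medians relative to the shift of all genes were 3.44, 3.08, 2.19, 2.18, 1.23 and 1.16 in that order. Camera's adjusted p with an estimated correlation was 0.357 to 0.632 for these 6 lists.

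The 2 other subtype lists moved less. In the classical glioma list 10 of 14 rose, 1 fell and 3 did not pass (the same adjusted over the list alone), and the score rose by 1.25 (adjusted p = 2.56e-05, or 0.642 with an estimated correlation). EGFR, the receptor often amplified in glioblastoma, averaged 4.95 ± 2.08 FPKM in brain and 161 ± 321 in core (log2 change 2.75, SE 0.60, adjusted p = 3.48e-05), while FGFR3 fell by 1.94. In the proneural glioma list 3 of 15 rose, 3 fell and 9 did not pass, and 9 of its members stand in another list. SOX4 (2.80) and SOX11 (2.37) rose, whereas PDGFRA (0.85, adjusted p = 0.113) and OLIG2 (-0.07, adjusted p = 0.869) did not pass. Its score differed by 0.34 (adjusted p = 0.316).

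All 12 tested members of the monocyte and macrophage list rose at least 2-fold (12 adjusted over the list alone). The scavenger receptor CD163 went from 2.58 ± 1.20 FPKM in brain to 150 ± 144 in core (log2 change 4.77, SE 0.46, adjusted p = 2.25e-15), with S100A9 (3.77) and VSIG4 (3.23) next. Of the microglia list 6 of 11 rose, 3 fell and 2 did not pass (the same adjusted over the list alone). The purinergic receptor P2RY12, typical of resting microglia, fell by 1.81, and the score difference of 0.47 did not pass (adjusted p = 0.0733). Of the common myeloid list 11 of 12 rose (11 adjusted over the list alone), including C1QA, C1QB and C1QC (2.41, 2.32 and 2.24). Complement had 13 of 14 higher and 1 lower (CD55, -0.84), with C1R (3.81), CFI (3.64) and C4B (2.76) leading. Antigen presentation and interferon had 16 of 18 higher, with GBP1 (3.32) and HLA-B (3.29), and chemokines 13 of 16, with CCL2 (3.78), CXCL10 (2.90) and IL8 (2.60). T and NK lymphocyte genes rose in 10 of 12 cases (10 adjusted over the list alone), from low levels, as with CCL5, at 0.942 ± 0.486 FPKM in brain and 6.61 ± 8.72 in core. Scores rose by 2.73 for macrophages, 1.75 for myeloid cells, 2.25 for complement, 1.97 for antigen presentation and 1.56 for chemokines (adjusted p = 2.56e-05 each), and by 0.83 for lymphocytes (adjusted p = 0.00016). Of the B and plasma cell list only 2 members could be tested and 1 rose (IGJ, 1.56), with a score difference of 0.61 (adjusted p = 0.0229) that was -0.0038 within series A. Adjusted over the list alone the other member fell, and camera gave the list a downward direction. Camera's adjusted p with an estimated correlation was 0.570 to 0.884 over the 7 lists with a passing score.

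Vessel lists split. In the endothelial list 5 of 12 rose, 2 fell and 5 did not pass. ANGPT2 (2.56) and ESM1 (2.21), both made by sprouting endothelium, rose, and TEK (-1.01) and TIE1 (-0.74), receptors of resting vessels, fell. The score rose by 0.45 (adjusted p = 0.0292), but camera gave it a downward direction (adjusted p = 0.884 with an estimated correlation), and with median-of-ratios scaling it differed by 0.13 (adjusted p = 0.531). The mural list had 6 of 11 higher, with LUM (2.62) and ACTA2 (2.18), 1 lower (the pericyte gene RGS5, -1.24) and 4 not passing, and its score rose by 0.83 (adjusted p = 0.000261), or 0.47 with median-of-ratios scaling. All 6 tested ependymal and choroid plexus genes rose, led by AQP1 (2.69) and FOXJ1 (2.32), with a score difference of 1.78. None of 3 red blood cell genes passed (score difference 0.56, adjusted p = 0.375). Immediate early genes, which respond within minutes to handling and stress, rose in 13 of 15 cases, with FOS (3.297), ZFP36 (2.68) and JUN (2.28), and a score difference of 1.60. All 18 ribosomal protein genes rose, 2 of them at least 2-fold (RPS2, 1.65, and RPL23, 1.01), with a score difference of 0.79 that was 0.37 with median-of-ratios scaling. These counts stayed as given when adjusted over each list alone. The ependymal, immediate early and ribosomal scores had an adjusted p of 2.56e-05, and camera with an estimated correlation gave 0.645 for each of them and 0.837 for the mural list. Outside the lists, AP005264.1 and MT-CO1 had log2 changes of 6.42 and 5.83 but were listed at 0 in 11 and 9 of 17 brain samples, and MT-CO1 averaged 8092 ± 4478 FPKM in core and 9629 ± 11368 in brain, so its log2 change came from the zeros, which can be failed estimates.

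**Figure D2:**
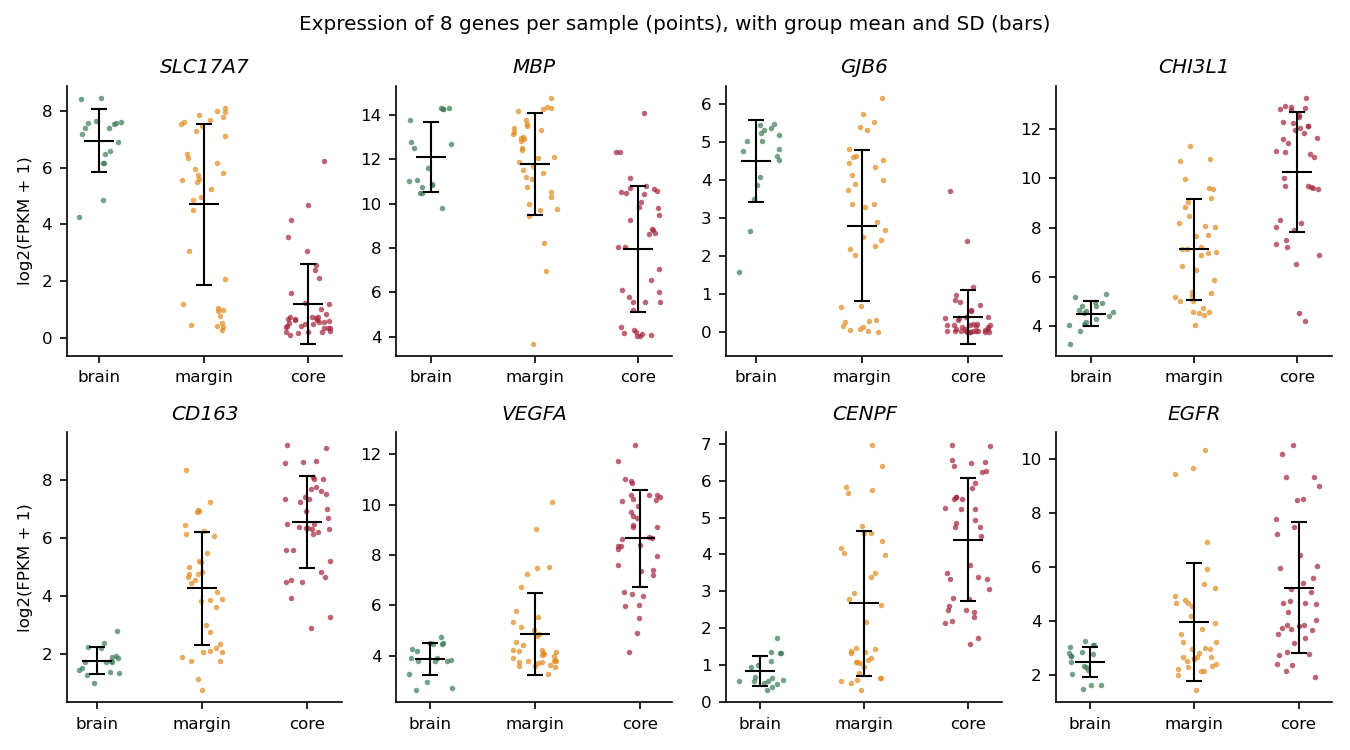
Expression of 8 genes as log2(FPKM + 1) on the y axis, for the samples of each group on the x axis (17 brain, 36 margin, 39 core), with points for samples and bars for the group mean and SD. SLC17A7, MBP and GJB6 are lowest in core and CHI3L1, CD163, VEGFA, CENPF and EGFR highest, with the margin mean between the others in each case.

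Margin samples held less RNA of neurons and more of reactive astrocytes and macrophages than brain. For myelin genes the tests disagreed, as given below. SERPINA3 rose from 8.44 ± 6.72 FPKM in brain (SD, n = 17) to 293 ± 268 in margin (n = 36), a log2 change of 4.62 (SE 0.44, adjusted p = 4.97e-13). MBP averaged 7620 ± 7718 in brain and 7283 ± 7061 in margin, a log2 change of -0.30 (SE 0.71, adjusted p = 0.757). In all, 610 genes were called higher and 428 lower in margin than in brain, against 362 and 688 with median-of-ratios scaling. Within series A 1168 were higher and 368 lower, and with title series as a covariate 1029 and 458.

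All 15 neuron genes fell in margin, 13 of them at least 2-fold (15 adjusted over the list alone), with VSNL1 (-2.38), NEFL (-2.36), CAMK2A (-2.25) and RBFOX3 (-1.75). The score fell by 1.89 (SE 0.50, adjusted p = 0.00375). Interneuron genes fell in 7 of 12 cases, with CCK (-2.09) and SST (-2.01), and glutamate receptor genes in 7 of 12 (8 adjusted over the list alone), with GRIN1 (-2.15) and CAMK2B (-1.40). Their scores fell by 1.09 (adjusted p = 0.0044) and 0.71 (adjusted p = 0.0197). List medians relative to the shift of all genes were -2.23, -1.25 and -0.86. Within series A, with 10 margin and 8 brain samples, these 3 scores differed by -2.19, -1.15 and -0.69 and no longer passed (permutation adjusted p = 0.064, 0.0882 and 0.243). Of 15 mature oligodendrocyte genes only OPALIN passed (-1.63, adjusted p = 0.00788), and the score difference of -0.28 did not (SE 0.43, adjusted p = 0.549). It was -1.17 within series A and -0.85 with title series as a covariate (permutation adjusted p = 0.225 and 0.252), and camera called the list lower at the preset correlation (adjusted p = 0.0192) but not at an estimated correlation (adjusted p = 0.675). The astrocyte list had 3 higher, 3 lower and 9 not passing, with GFAP at 1.49 and GJB6 at -1.70, and its score differed by 0.12 (adjusted p = 0.455), a difference of -0.11 with median-of-ratios scaling. In the oxidative phosphorylation list 3 of 18 fell (1 adjusted over the list alone), with NDUFB8 at -0.59, and the score differed by -0.15 (adjusted p = 0.0977), or by -0.39 with median-of-ratios scaling (adjusted p = 0.000212). Within series A this score went the other way, by 0.0584, and did not pass. Camera with an estimated correlation called none of these lists, at an adjusted p of 0.357 for the neuron and interneuron lists and 0.452 for the glutamate list.

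Of the tumour state lists, reactive astrocyte genes rose in 13 of 13 cases, each at least 2-fold, with CHI3L2 (3.002) beside SERPINA3, and the score rose by 2.19. All 20 proliferation genes rose, 17 at least 2-fold, with UBE2C (2.24), TOP2A (1.89) and MKI67 (1.45), and a score difference of 1.43 (adjusted p = 0.000465). Mesenchymal genes rose in 15 of 20 cases, with CD44 (2.62) and CHI3L1 (2.61), and matrix genes in 11 of 18 (12 adjusted over the list alone), with TNC (2.66), TIMP1 (2.62) and SPARC (2.27), at score differences of 1.29 (adjusted p = 2.56e-05) and 1.36 (adjusted p = 0.000269). Only 5 of 17 hypoxia genes rose (4 adjusted over the list alone), with ADM (1.46) and HK2 (1.16), and the score rose by 0.52 (adjusted p = 0.000689), while VEGFA at 0.98 did not pass (adjusted p = 0.0948). Stem genes rose in 9 of 14 cases, with ID3 (2.13), NES (1.82) and SOX2 (1.10), and classical genes in 8 of 14, with EGFR at 1.47 (adjusted p = 0.0464). Scores rose by 0.96 for stem, 0.68 for classical, 0.67 for proneural (adjusted p = 0.0105) and 0.47 for progenitor genes (adjusted p = 0.0472). The last 2 lists had 4 of 15 and 4 of 14 members higher (3 and 1 adjusted over the list alone), with DLL3 (1.65) and PTPRZ1 (1.44), and with median-of-ratios scaling their scores no longer passed (adjusted p = 0.0559 and 0.245). With an estimated correlation camera's adjusted p for these lists was 0.357 for reactive astrocytes and 0.452 to 0.875 for the rest.

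Immune lists rose in margin as well. Macrophage genes rose in 9 of 12 cases (10 adjusted over the list alone), with VSIG4 (2.49) and CD163 (2.48, from 2.58 ± 1.20 to 42.3 ± 62.3 FPKM). Microglia genes rose in 7 of 11 (8 adjusted over the list alone) and none fell, with CCL3 (1.99) and SLC2A5 (1.42). Myeloid genes rose in 10 of 12 (12 adjusted over the list alone), complement in 13 of 14, with C4B (2.24) and C4A (2.23), antigen presentation in 14 of 18, with HLA-B (1.77) and GBP1 (1.72), and chemokines in 9 of 16, with CCL2 (2.52) and CCL4 (2.06). Only 2 of 12 lymphocyte genes rose (1 adjusted over the list alone), CCL5 (1.01) and CD3D (0.64). Scores rose by 1.48 for macrophages, 0.74 for microglia, 1.21 for myeloid cells, 1.35 for complement, 1.08 for antigen presentation, 1.005 for chemokines and 0.41 for lymphocytes (adjusted p = 2.56e-05 to 0.00396). Within series A the microglia (0.66), myeloid (1.12) and chemokine (0.79) scores did not pass (permutation adjusted p = 0.114, 0.064 and 0.0834). Neither B and plasma cell gene passed, though their score rose by 0.33 (adjusted p = 0.0406), which was 0.05 within series A. Camera's adjusted p with an estimated correlation was 0.527 to 0.884 over these lists.

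Among the remaining lists, endothelial genes rose in 3 of 12 cases and fell in 1 (TEK, -0.40), with ANGPT2 (1.41) and VWF (0.88), and mural genes rose in 2 of 11, ACTA2 (1.13) and TAGLN (1.10). Ependymal and choroid plexus genes rose in 4 of 6, with AQP1 at 3.07, and 1 of 3 red blood cell genes rose (HBA2, 1.39). Immediate early genes rose in 11 of 15 cases, with FOS (2.67), ZFP36 (1.996) and JUNB (1.65), and ribosomal genes in 15 of 18, none of them 2-fold. Score differences were 0.44 for each vessel list (adjusted p = 0.00171 and 0.0173), 1.17 for ependymal, 1.19 for red blood cell (adjusted p = 0.0267), 1.16 for immediate early (adjusted p = 0.000713) and 0.47 for ribosomal genes (adjusted p = 0.00309). The immediate early score was 0.52 within series A (permutation adjusted p = 0.378), and the mural, red blood cell and ribosomal scores did not pass with median-of-ratios scaling (adjusted p = 0.169, 0.082 and 0.0886). Camera with an estimated correlation gave an adjusted p of 0.576 to 0.837 for these lists. Outside the lists, the synaptic genes CABP1 (-2.52) and RPH3A (-2.48), and values listed for the small nucleolar RNA SNORA8 (-2.65) fell by the largest steps among named genes. Libraries were of polyadenylated RNA and overlapping transcripts could not be told apart, so the SNORA8 values need not be of that RNA. MT-CO1 (6.64), MIR1282 (4.14) and AP005264.1 (3.15) rose but were listed at 0 in 9, 11 and 11 of 17 brain samples.

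**Figure D3:**
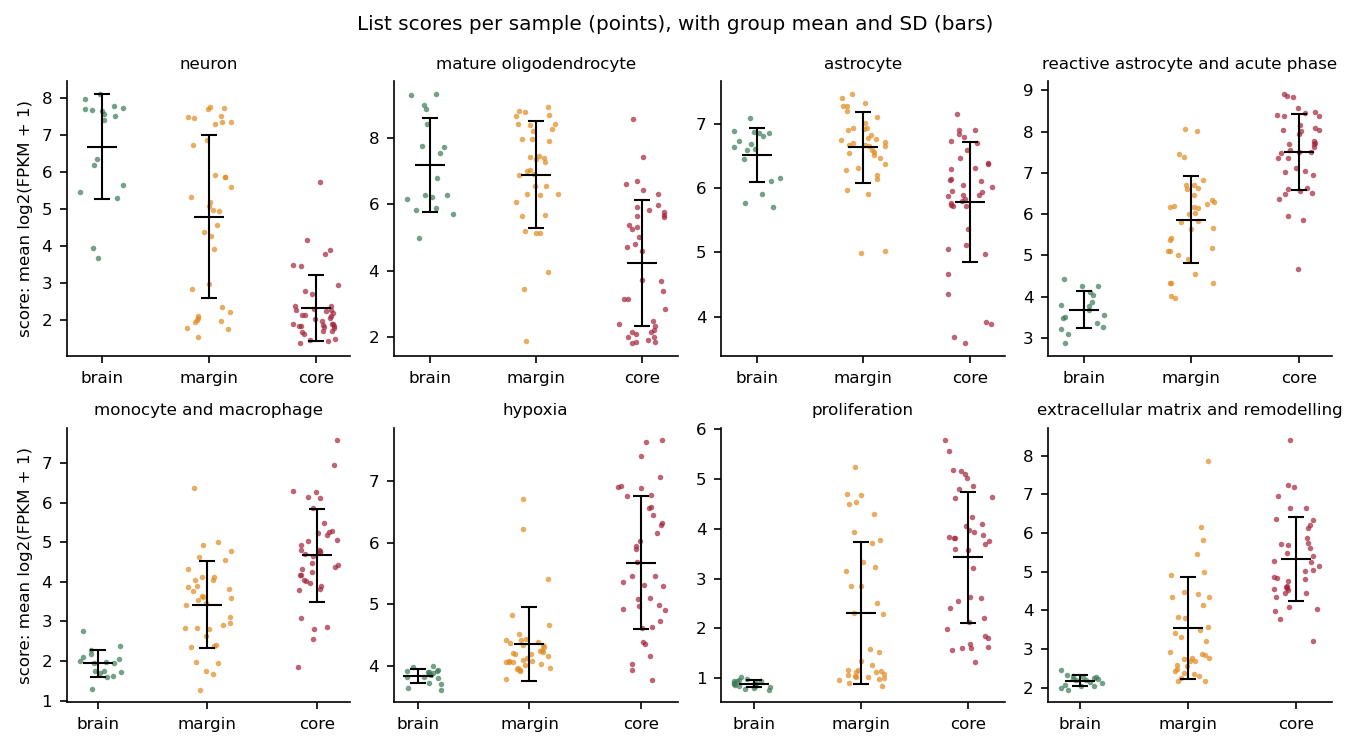
Score of 8 gene lists (mean log2(FPKM + 1) over members, y axis) per sample for brain (n = 17), margin (n = 36) and core (n = 39), with bars for the group mean and SD. The neuron score falls from 6.68 in brain to 4.79 in margin and 2.32 in core, and the mature oligodendrocyte score is 7.17, 6.89 and 4.22.

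Core against margin set hypoxia, matrix and mesenchymal genes in the core against myelin, neuron and astrocyte genes in the margin. VEGFA averaged 823 ± 1030 FPKM in core (SD, n = 39) and 78.7 ± 199 in margin (n = 36), a log2 change of 3.81 (SE 0.37, adjusted p = 2.40e-13), above the margin median in 38 of 39 core samples. MBP fell by 3.84 (SE 0.56, adjusted p = 1.47e-08). Outside the lists the methyltransferase NNMT (3.69), the transporter ABCC3 (3.51) and the growth factor binding protein IGFBP2 (3.34) rose most, and AGXT2L1, an astrocyte enzyme, fell by 3.53. In all, 692 genes were called higher and 1009 lower in core than in margin, against 467 and 1272 with median-of-ratios scaling. Within series A (13 core, 10 margin) 704 and 853 were called, and within the second title series, called series B (23 core, 23 margin), 715 and 1079. Of the 692 and 1009 genes, 451 and 681 were called the same way within series A and 514 and 921 within series B.

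All 15 mature oligodendrocyte genes fell at least 2-fold (15 adjusted over the list alone), with MOBP (-3.64) and OPALIN (-3.49) beside MBP, and the score fell by 2.66 (SE 0.41, adjusted p = 2.56e-05), or by 3.25 within series A and 2.20 within series B. Neuron genes fell in 13 of 15 cases (13 adjusted over the list alone), with SLC17A7 (-3.50), VSNL1 (-3.48) and RBFOX3 (-2.01), and the score fell by 2.48, by 2.02 within series A and by 2.80 within series B. Interneuron genes fell in 10 of 12, with CCK (-3.34), SST (-2.76) and NPY (-2.49). Of the glutamate list 7 of 12 fell, with GRIN1 (-3.38), and 2 rose, with NLGN1 at 0.64. Astrocyte genes fell in 11 of 15 cases, with GJB6 (-2.40) and SLC1A2 (-1.89), and SOX9 rose by 0.80. Interneuron, glutamate and astrocyte scores fell by 1.47, 0.78 and 0.85 (adjusted p = 2.56e-05 each). The glutamate score differed by -0.62 within series A (permutation adjusted p = 0.0705). Of 18 oxidative phosphorylation genes 6 fell, with NDUFB8 (-0.71), and the score by 0.15 (adjusted p = 0.0351), though within series A it differed by -0.06 (permutation adjusted p = 0.697). With an estimated correlation camera's adjusted p was 0.375 to 0.635 over these lists.

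List medians relative to the shift of all genes were 1.03 for hypoxia, 1.81 for matrix, 1.17 for mesenchymal and -3.04 for mature oligodendrocyte genes. Hypoxia genes rose in 13 of 17 cases (13 adjusted over the list alone), with CA12 (2.64) and CA9 (2.61), both carbonic anhydrases, and the score rose by 1.32 (SE 0.20), 1.95 within series A and 0.93 within series B. Matrix genes rose in 17 of 18, with TIMP1 (2.49), COL4A1 (2.46) and TNC (2.42), mesenchymal genes in 17 of 20, with CHI3L1 (3.16) and TGFBI (3.14), and reactive astrocyte genes in 13 of 13, with VIM (1.98). Their scores rose by 1.79, 1.43 and 1.64 (adjusted p = 2.56e-05 each, as for hypoxia), by 2.09, 1.94 and 2.26 within series A and by 1.58, 1.15 and 1.29 within series B. Proliferation genes rose in 19 of 20 cases (20 adjusted over the list alone), with CENPF (1.73), RRM2 (1.62) and MKI67 (1.19), and the score rose by 1.12 (adjusted p = 0.0013), by 0.80 within series A (permutation adjusted p = 0.137) and 1.08 within series B. Stem genes rose in 9 of 14, with NES (2.01), FABP7 (1.56) and SOX2 (1.02), and classical genes in 9 of 14, with JAG1 (1.34) and EGFR (1.27), while FGFR3 fell by 1.66. Their scores rose by 0.71 and 0.57, and did not pass within series A (0.50 and 0.55, permutation adjusted p = 0.106 and 0.1). Progenitor genes went both ways, with 6 of 14 lower and 3 higher, and proneural genes too, with 6 of 15 lower and 2 higher. GPR17 (-1.81), SOX10 (-1.60) and ERBB3 (-1.90) fell, and PTPRZ1 (1.41), SOX4 (1.24) and SOX11 (1.11) rose. Neither score passed (-0.20, adjusted p = 0.407, and -0.33, adjusted p = 0.231), but both fell within series A, by 0.86 and 0.97 (permutation adjusted p = 0.00495 and 0.0157). Camera's adjusted p with an estimated correlation was 0.452 to 0.799 over these lists.

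All 12 macrophage genes were higher in core than in margin (12 adjusted over the list alone), with CD163 (2.29), S100A9 (1.52) and CLEC5A (1.45), while 5 of 11 microglia genes fell, 1 rose and 5 did not pass, with P2RY12 at -1.46. The macrophage score rose by 1.24 (adjusted p = 4.83e-05) and the microglia score differed by -0.27 (adjusted p = 0.192). Antigen presentation genes rose in 13 of 18 cases, with GBP1 (1.60) and HLA-B (1.53), complement genes in 9 of 14, with C1R (2.03), CFI (1.66) and SERPING1 (1.37), and CD55 fell by 0.50. Chemokine genes rose in 10 of 16, with CXCL10 (1.67), IL8 (1.30) and CCL2 (1.26), myeloid genes in 7 of 12, with CD68 (0.87), and lymphocyte genes in 8 of 12, with IL7R (0.72) and PRF1 (0.69). Scores rose by 0.89 and 0.90 for antigen presentation and complement (adjusted p = 0.000269 and 0.000541), and by 0.55, 0.54 and 0.42 for chemokines, myeloid cells and lymphocytes (adjusted p = 0.0124, 0.0443 and 0.00849). Within series B the chemokine and myeloid scores were 0.26 and 0.40 (permutation adjusted p = 0.408 and 0.295), and within series A the lymphocyte score was 0.38 (permutation adjusted p = 0.2). The 2 B and plasma cell genes went apart, with IGJ at 1.16 and POU2AF1 at -0.61. Endothelial genes rose in 2 of 12 cases, the tip cell genes ESM1 (1.49) and ANGPT2 (1.14), and fell in 3, and the score differed by 0.01 (adjusted p = 0.928) against a list median of -0.23. Mural genes rose in 5 of 11, with LUM (1.90) and ACTA2 (1.05), and RGS5 fell by 0.92. Ependymal genes rose in 5 of 6, with FOXJ1 (1.003) and C1orf88 (0.86), ribosomal genes in 12 of 18 (13 adjusted over the list alone), with RPS2 (0.79) and RPS18 (0.44), and immediate early genes in 6 of 15 (5 adjusted over the list alone), with JUN (1.10) and DNAJB1 (1.003). Mural, ependymal and ribosomal scores rose by 0.39, 0.61 and 0.32 (adjusted p = 0.0339, 0.0171 and 0.0113) and did not pass with median-of-ratios scaling (0.23, 0.49 and 0.13). The ependymal score was 0.23 within series A (permutation adjusted p = 0.388). Without 6 core samples of series B whose scores lay over those of any margin sample, a choice made after seeing the data, it was 0.19 (permutation adjusted p = 0.326), with FOXJ1 at 0.42 and C1orf88 at 0.302. The chemokine and myeloid scores did not pass with that scaling either (0.43 and 0.37). The immediate early score, at 1.21, passed within series A only (permutation adjusted p = 0.0113), and pooled neither it nor the red blood cell score did (0.44, adjusted p = 0.0878, and -0.63, adjusted p = 0.217). Camera with an estimated correlation gave an adjusted p of 0.576 to 0.875 for all lists of this kind.

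**Figure D4:**
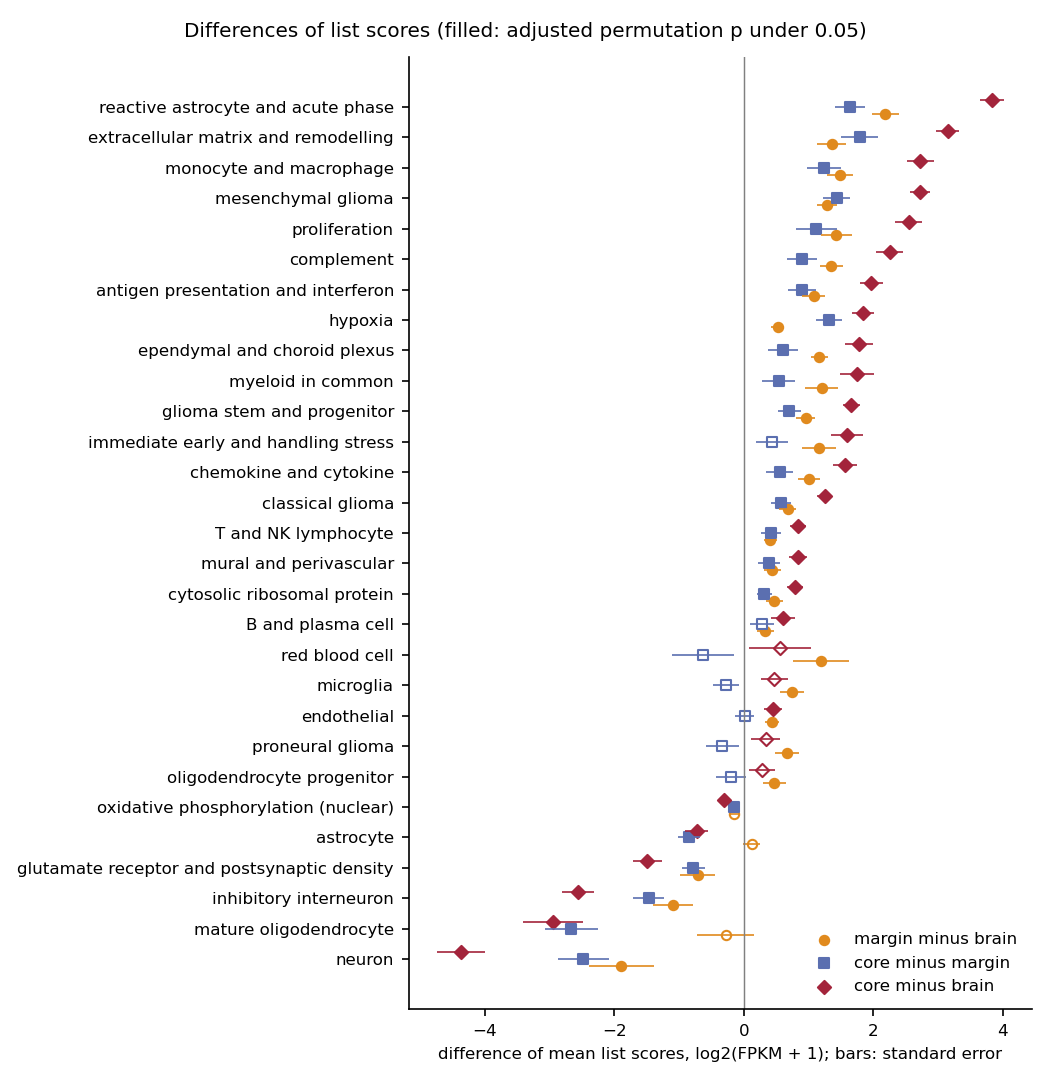
Difference of mean list score (x axis, log2(FPKM + 1)) for each of 29 gene lists (y axis) in the 3 comparisons, with bars for the standard error of the difference and filled symbols for an adjusted permutation p under 0.05. The neuron list shows the largest fall from brain to core (-4.36) and the reactive astrocyte list the largest rise (3.83), while the mature oligodendrocyte list falls between margin and core (-2.66) and its difference between brain and margin (-0.28) does not pass.

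The margin mean lay between brain and core for nearly all genes called between those groups. Choosing genes by that difference favours a mean in between, and no expected share was computed. The position is one of group means, as single margin samples ran across most of the span from brain to core. Of the 3000 genes higher in core, 99.0% had a margin mean between the others, at a median of 0.480 of the distance from brain to core (quartiles 0.400 and 0.562), 23 had a margin mean beyond the core and 6 lay on the opposite side of brain. Of the 1821 lower genes 94.9% lay between, at a median of 0.414 (quartiles 0.272 and 0.504), 5 beyond and 88 opposite. Fold changes of core and margin against brain correlated at r = 0.893 across genes, which are not independent replicates. Both used the same brain samples, and simulated unchanged groups against those samples gave r = 0.539 on average (-0.00793 to 0.837 in 100 simulations). The covariance was 0.434 against 0.0201 in the simulations (-0.000248 to 0.0666), a difference of 0.414. With the brain samples split into sets of 8 and 9, the median over 20 splits was r = 0.846 and the covariance 0.420. Of the genes called higher and lower in margin, 581 of 610 and 424 of 428 were also called that way in core, against 94.6 and 40.3 for independent lists, and medians of 501.5 (353 to 657) and 314.5 (78 to 655), of median margin calls of 529.5 and 324, with split brain samples.

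Only 5 genes were highest in margin, that is called higher than in both brain and core, and 0 were lowest by limma. At unadjusted p under 0.05 in both comparisons and no bound on size, 162 were highest and 32 lowest. PI16, a secreted peptidase inhibitor, averaged 27.3 ± 20.1 FPKM in margin, 11.6 ± 9.53 in brain and 9.90 ± 13.3 in core (log2 changes 1.10, adjusted p = 0.0295, and -1.71 from margin to core, adjusted p = 5.69e-06). The others were 4 transcripts known by clone names only, with margin means of 30.6 ± 42.7, 8.85 ± 12.5, 12.9 ± 9.95 and 12.7 ± 8.73 FPKM. Strand was not stated, so overlapping transcripts could not be told apart in these values. The count moved from 1 to 77 over the settings tried.

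The series title asks about subtype, and because no label gives the subtype of a sample, relations across samples between the 3 subtype scores and 9 cell type scores were computed in margin and in core, 54 in all. Mesenchymal scores rose with macrophage scores in both, at r = 0.905 in margin (rho = 0.943, n = 36, permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 6.75e-05) and r = 0.760 in core (rho = 0.628, n = 39, permutation p = 1e-05, adjusted p = 6.75e-05). The values were 0.784 and 0.703 within series A, 0.935 and 0.791 within series B, and 0.876 and 0.676 without the 2 farthest samples. These lists share no member, but macrophages also make CHI3L1 of the mesenchymal list. In bulk samples the same cells could therefore raise both scores. Mesenchymal scores also rose with lymphocyte scores (r = 0.707 in margin, 0.503 in core; rho = 0.778 and 0.460; adjusted p = 6.75e-05 and 0.00503), with 0.766 and 0.725 within series A and 0.719 and 0.495 within series B. The core value in series B did not pass (permutation adjusted p = 0.059). Proneural scores rose with progenitor scores after the 5 shared genes were left out (r = 0.876 in margin and 0.896 in core; rho = 0.875 and 0.866; adjusted p = 6.75e-05 each), with at least 0.760 in each series. They rose with proliferation in margin (r = 0.755, rho = 0.670, adjusted p = 6.75e-05; 0.632 within series A and 0.767 within series B) and in core (r = 0.653, rho = 0.640, adjusted p = 0.00018), but within series A the core value was -0.0167 against 0.718 within series B. The margin value in series A did not pass (permutation adjusted p = 0.156). Classical scores rose with proliferation in margin (r = 0.750, rho = 0.805, adjusted p = 6.75e-05; 0.891 and 0.623 within the series) and in core (r = 0.384, adjusted p = 0.0352; rho = 0.353, adjusted p = 0.0598; 0.542 and 0.447 within the series). Neither core value within the series passed (permutation adjusted p = 0.156 and 0.082).

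In margin each subtype score fell as the neuron score rose, at r = -0.448 for proneural, -0.616 for classical and -0.510 for mesenchymal (rho = -0.465, -0.662 and -0.570; adjusted p = 0.0163, 0.000216 and 0.00454). The values were -0.263, -0.613 and -0.879 within series A and -0.479, -0.556 and -0.414 within series B. Of these, only mesenchymal in series A and classical in series B passed (permutation adjusted p = 0.0139 and 0.01935). Mesenchymal scores in margin also rose with microglia (r = 0.540, rho = 0.664, adjusted p = 0.00279; 0.563 and 0.564 within the series) and endothelial scores (r = 0.537, rho = 0.631, adjusted p = 0.00378; 0.890 and 0.347), neither of which passed in core (r = 0.271 and -0.0537, adjusted p = 0.155 and 0.806). A permutation test of the difference in r between margin and core passed for neither (adjusted p = 0.26 and 0.0558). The microglia value in series A and the endothelial value in series B did not pass (permutation adjusted p = 0.229 and 0.207). The relation of classical and endothelial scores in margin (r = 0.514, rho = 0.401, adjusted p = 0.00503) was 0.221 without the 2 farthest samples, 0.828 within series A and 0.0338 within series B. In core, proneural scores fell as scores rose for macrophage (r = -0.454, rho = -0.393, adjusted p = 0.00961), lymphocyte (r = -0.484, rho = -0.590, adjusted p = 0.00454) and microglia lists (r = -0.393, rho = -0.399, adjusted p = 0.0338). The macrophage, lymphocyte and microglia values were 0.186, -0.104 and 0.351 within series A and -0.764, -0.532 and -0.453 within series B, so these relations did not hold within both. Classical scores fell as mature oligodendrocyte scores rose in margin (r = -0.591, adjusted p = 0.00191; rho = -0.370, adjusted p = 0.0584) and core (r = -0.450, rho = -0.408, adjusted p = 0.01). The values were -0.603 and -0.720 within series A and -0.604 and -0.209 within series B, and neither the margin value in series A (adjusted p = 0.168) nor the core value in series B (adjusted p = 0.486) passed. Of the 54 relations 27 passed by Pearson's r, 15 in margin and 12 in core, and 23 by both coefficients.

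**Figure D5:**
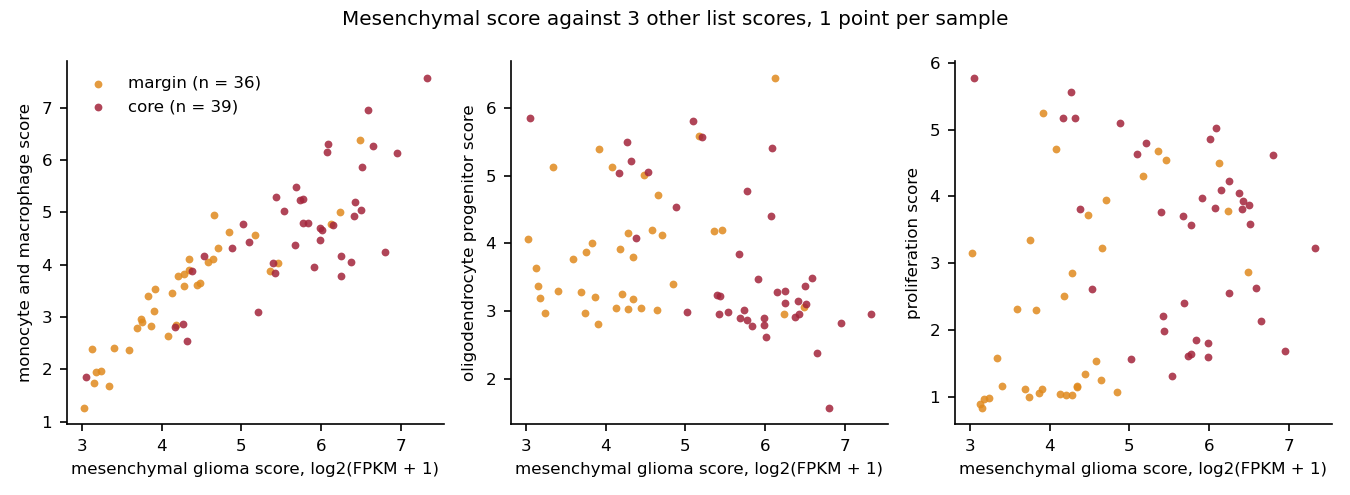
Mesenchymal glioma score (x axis) against the macrophage, oligodendrocyte progenitor and proliferation scores (y axes), all in log2(FPKM + 1), with a point for each margin (n = 36) and core (n = 39) sample. Macrophage scores rise with mesenchymal scores in both groups (r = 0.905 and 0.760), while progenitor scores fall in core (r = -0.697) and not in margin (r = 0.217).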

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

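The test of the share of brain tissue was chosen before its result was seen, and the tests within title series after. A test of the difference between margin and core set 4 of 27 relations apart, permuting the group labels. Proneural and neuron scores went against each other in margin and rose together in core (r = -0.448 and 0.475, difference -0.9226, adjusted p = 0.00027, the smallest the permutations gave). Within series A and B the margin values were -0.263 and -0.479 (adjusted p = 0.666 and 0.0633) and the core values 0.746 and 0.262 (adjusted p = 0.0175 and 0.354), so only the core value in series A passed. Classical and oligodendrocyte progenitor scores rose together in margin and did not in core (0.381 and -0.121, difference 0.5017, adjusted p = 0.0425), and the margin value passed in neither series (0.418 and 0.247, adjusted p = 0.411 and 0.354). Mesenchymal scores went against progenitor scores in core only (0.217 and -0.697, difference 0.914, adjusted p = 0.00513) and rose with proliferation scores in margin but not in core (0.508 and -0.358, difference 0.8655, adjusted p = 0.00801). That margin value passed in neither series (0.712 and 0.395, adjusted p = 0.0705 and 0.127). The core value passed by r (permutation adjusted p = 0.0496) but not by rank (-0.215, adjusted p = 0.299). It was -0.578 within series B (permutation adjusted p = 0.01935), 0.129 within series A (permutation adjusted p = 0.817) and -0.192 without the 2 farthest samples. The differences were -1.01, 0.708, 0.792 and 0.584 within series A and -0.740, 0.174, 0.998 and 0.973 within series B.

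A share of tumour that varies between margin samples could by itself give positive relations between lists that are higher in tumour. With neuron and mature oligodendrocyte scores removed from the margin scores, 43.65% (bootstrap SD 17.88) of the median difference in r was left over the 3 relations that do not involve neurons, so a varying share of tumour is consistent with part of the pattern. The differences left were 0.0643 for classical with progenitor, 0.560 for mesenchymal with progenitor and 0.378 for mesenchymal with proliferation scores, so most of the mesenchymal and progenitor difference stayed. All 4 differences, or 100%, kept their sign within series B, and 3 lay over 2 bootstrap SDs from 0 there (SD 0.240, 0.316 and 0.256), which argues against title series as their cause. The forms of description pooled in series B were not separated in this test. For classical with progenitor scores the value of 0.174 (SD 0.262) cannot tell. In core, mesenchymal scores fell as progenitor scores rose (r = -0.697; -0.372 within series A, adjusted p = 0.406, and -0.901 within series B), and the test on shares of tumour removed nothing from the core scores, so it says nothing about that relation. Whether margin cells hold it too stayed open, as a bulk sample does not tell cells apart.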

How the results depend on the processing

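Alternatives were chosen before the data were examined, except leaving out copied libraries, zeros, names without protein-coding match, repeated symbols, 6 core samples with high ependymal scores, or mitochondrial and top genes from the scaling. No gene was called the opposite way in any of them. With a pseudocount of 0.1, 1507 genes were higher and 788 lower in margin than brain, 1367 higher and 1802 lower in core than margin, 17 highest and 1 lowest in margin; with 0.5, 11 were highest. A mean of at least 5 FPKM left 1200 lower in core than brain, from fewer genes tested. Median-of-ratios scaling gave 1709 higher in core than brain, 362 higher and 688 lower in margin than brain and 2 highest in margin, and quantile normalization 1951, 383 and 3 (higher calls and highest). Title series as a covariate gave 1029 higher in margin than brain and 2 highest, and series A alone 1168 higher. Array weights gave 785 lower in margin than brain, 1123 higher in core than margin, 77 highest, 29 lowest and a correlation of fold changes of 0.806. Protein-coding names left 1 highest in margin. Without mitochondrial and top genes in the scaling, 784 were lower in margin than brain, 1568 lower in core than margin and 8 highest. Without the 6 core samples the ependymal score from margin to core was 0.1922 and its spread 0.1469, and neither passed. Camera with an estimated correlation called 0 lists. Within series A 14 and within series B 15 relations passed, with fewer samples. A value was counted as reversed where its sign changed and it passed before or after the change. Sign changes where neither value passed also occurred and are not listed here. Reversed values were the B and plasma cell score from brain to core in series A (-0.0038) and with the covariate (-0.0327), NDUFA4 from brain to margin with the covariate (0.0061), SOX6 from margin to core in series A (-0.24), and in core in series A the relations of proneural with microglia (0.3511), macrophage (0.1855) and proliferation (-0.0167) and of mesenchymal with astrocyte (-0.7426) and proliferation scores (0.1285). The cause was not tested where none is given. Of 1243 list comparisons 1158 stayed as they were, 71 were weaker and 12 stronger; of 4520 for named genes 4375 stayed, of 437 for spreads 397 and of 378 for relations 336. Shared patients were not testable, and low values were limited by depth.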

Other observations

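Samples of a group differed more in some lists than in others. Hypoxia scores spread wider in core than in margin (mean absolute deviation 0.92 and 0.32, adjusted p = 0.000348, the smallest the permutations gave), as did endothelial (0.64 and 0.37, adjusted p = 0.013) and ependymal scores (0.96 and 0.49, adjusted p = 0.0206). Without the 6 core samples whose ependymal scores lay over those of any margin sample, the core value was 0.64 and the difference did not pass (adjusted p = 0.317). Neuron scores spread wider in margin (1.88, against 0.57 in core, adjusted p = 0.000348), as did interneuron (1.08 and 0.47) and glutamate receptor scores (0.79 and 0.30). Proliferation scores hardly differed between brain samples (0.06) but did in margin (1.22, adjusted p = 0.00087) and core (1.10, adjusted p = 0.000348). Of 87 spread differences 39 passed.

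Neuron and mature oligodendrocyte scores went against each other in brain (r = -0.921, rho = -0.924, n = 17, permutation p = 1e-05, the smallest 100000 resamples can give, adjusted p = 3e-05; -0.939 within series A), as grey and white matter do. In margin neither coefficient passed (r = -0.011, permutation adjusted p = 0.949, and rho = -0.161, adjusted p = 0.349). In core they rose together by rank (rho = 0.379, permutation adjusted p = 0.0262), while r did not pass (0.292, adjusted p = 0.105).

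The first test of this pattern, and the limit to the range of brain samples in the second, were chosen after the result was seen. Mature oligodendrocyte scores fell in core, and their difference from brain in margin did not pass, while neuron scores fell in both. Within series A neither margin difference passed (-1.17 and -2.19), and camera at the preset correlation called both lists lower in margin. On the FPKM scale from the core level (0%) to the brain level (100%), margin samples lay at 44.7% (SD 11.9) for neuron genes and 91.0% (SD 34.4) for oligodendrocyte genes, a difference of 46.33 (SD 42.77) that cannot tell whether tumour replaced both alike. More white matter in the margin samples as the only cause was tested by the line through the brain samples, and margin oligodendrocyte scores lay at -1.998 (SD 0.501) from it. 75.5% of this came from 12 of 36 samples with neuron scores below those of any brain sample, where the line is extrapolated, and the other 24 lay at -0.73 (SD 0.35), which argues against that cause by little more than 2 SDs. Where the brain samples were taken relative to white matter stayed open.

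The test of the next pattern was chosen after its result was seen. More genes were called higher than lower in core than in brain (3000 and 1821), and brain holds more of its FPKM in few abundant genes. With those genes left out of the scaling the median change of all genes was 0.1051, from 0.34, and 2476 genes were higher and 2714 lower. The excess of higher calls thus depended on the scaling, and median-of-ratios scaling turned it around as well. As a median change of 0.1051 was left, the test could not tell whether scaling accounts for the whole shift of all genes.

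In splits of the same samples at random, as many genes were called in 1 of 100 splits, the real grouping itself, for higher and lower calls of each comparison, against at most 4, 23, 368, 171, 165 and 121 genes in other splits for core against brain, margin against brain and core against margin (higher and lower calls of each). For genes highest or lowest in margin, unlike the counts above, the labels of all 3 groups were redrawn. This also removed the difference between core and brain. For the 5 genes highest in margin 2 of 100 splits called as many, the other with 69 genes. That is no chance level for margin genes with real core and brain samples. For the 0 lowest genes 100 of 100 splits called as many, so that count tells nothing.

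3 hypotheses were fixed before the data were examined. Core samples with higher hypoxia scores held higher mesenchymal scores (r = 0.6415, rho = 0.627, adjusted p = 6e-05; 0.400 in series A and 0.663 in series B; margin r = 0.663). Lower proliferation at higher hypoxia was not found (r = 0.1062, adjusted p = 0.516; 0.514 and -0.121 within the series; margin r = 0.449, adjusted p = 0.00541, and 0.295 without the 2 farthest samples). Macrophage and microglia scores rose together, against the hypothesis (r = 0.5981, rho = 0.571, adjusted p = 0.000135; 0.321 and 0.765; margin r = 0.724).

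Core minus margin differences of list scores did not differ between the series after adjustment (lowest adjusted p = 0.315, for hypoxia at 1.95 and 0.93 and immediate early genes at 1.21 and -0.04).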
